A study of Mus musculus with 3 samples.

How the data were processed

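Droplet single-cell RNA was measured in cells dislodged from the intima of the lesser curvature of the aortic arch of C57BL/6J mice, after perfusion with the transcription blocker actinomycin D and a short digestion with collagenase D and DNase I, per the labels. Libraries were made with the 10x 3' v3 kit. There were 3 libraries, 2 of untreated mice and 1 of mice given LPS, each pooling 5 to 10 animals. The labels do not number the replicates, so control replicates 1 and 2 are named in the order of their records. Nothing beyond the pooling says how far the libraries are separate experiments. So p-values rest at most on the spread between these samples, shared across genes as given below, which may be technical.

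The deposited values are raw UMI counts per gene and barcode, made by the authors with Cell Ranger 3.1, per the submitters' processing notes, which also name R 4.2.1, Seurat 4.2.0 and the mm10 assembly. The annotation release and the rule that selected barcodes are not given in the sources used here. No other values and no cell annotation of the authors were used. Counts covered 32285 genes. The smallest barcode held 501, 1117 and 1750 UMIs in the controls and the LPS library, so barcodes were selected at different depths.

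Computed here from those counts were cell classes, sums per class and tests. Barcodes with at least 500 UMIs, at least 300 genes and at most 15% mitochondrial UMIs were kept, 8284 of 12082. In control replicate 1, 628 barcodes fell under the gene minimum and 337 exceeded the mitochondrial limit, against 0 and 2116 in control replicate 2 and 36 and 810 in the LPS library. Scrublet, run per library, marked 6 barcodes, and these were removed. Libraries were clustered together without batch integration (scanpy 1.11.5, leidenalg 0.10.2, 10000 UMIs per cell as target sum, 2000 variable genes, 30 principal components, 15 neighbours, Leiden resolution 1.0, fixed seed).

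Clusters were named from markers of 17 cell classes. Clustering in 1 step mixed classes and left 0, 0 and 218 endothelial-like and 0, 0 and 162 fibroblast-like cells in the controls and the LPS library, so each cluster of at least 40 barcodes was clustered again (resolution 0.5, 20 principal components). That step was chosen after seeing the data, and endothelial-like, fibroblast-like and smooth muscle-like results rest on it. A sub-cluster took a name when the markers of a class exceeded their background by a log2 value of 1.5 and the next class by 0.5, with at least 3 markers detected in 10% of cells at 2-fold. It stayed unnamed where another class had more markers among its top 10 genes. This naming rule was the second tried. The first counted markers over the rest of the library and left 1 LPS endothelial-like sub-cluster unnamed, because Lcn2 is among the neutrophil markers, and its counts are given with the alternatives.

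By design, mononuclear phagocyte-like cells pool 1-step clusters named macrophage, dendritic or monocyte, but all were macrophage. A first test used sub-clusters, adding phagocytes of a mixed cluster (81, 208 and 366 cells). It called 296 genes higher and 156 lower, 213 and 80 among the main calls. The class was then set back to the design, with this version as an alternative. Near-empty barcodes are those of unnamed sub-clusters with at least 40% Gm42418. Shares are of named cells without erythroid-like ones, with Clopper-Pearson 95% intervals.

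UMIs were summed per library and class, since cells are not replicates, and classes with at least 20 cells in every library were tested. The test was edgeR 4.0.16's quasi-likelihood test with TMM factors, filterByExpr and Benjamini-Hochberg adjustment at 0.05. With 2 control libraries against 1, a single residual degree of freedom carries the spread, and the LPS library is assumed to vary like the controls. CPM values of tested genes are scaled by TMM factors, and those of S1P genes across classes are per all UMIs of the class, with exact Poisson 95% intervals. The difference between the responses of both classes was tested as an interaction with library as a block. The 24 gene lists were tested with camera in limma 3.58.1 on voom values, at a preset correlation of 0.01 and with an estimated correlation, for lists with at least 5 measured genes. With an estimated correlation 0 lists were called in any class, where the smallest unadjusted p was 0.0445 in endothelial-like, 0.0609 in phagocyte-like, 0.0665 in fibroblast-like and 0.0366 in lymphoid-like cells.

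The comparisons, the tests, the gene lists, the markers, the cell filter and the rule for named genes were fixed before the data were examined. By that rule up to 12 genes each way were named per main class, those with the largest fitted change among genes that passed with a mean of at least 20 CPM and the LPS value outside both controls. For other classes 5 each way were named, filled where fewer passed with genes of at least 50 UMIs in a sum. Predicted genes, mitochondrial, ribosomal protein, haemoglobin and sex-linked genes were left out of it. From each list up to 4 members that passed were named, or the 2 with the highest mean CPM where none did, and 13 genes of S1P signalling and leukocyte traffic were always named. Clock genes, genes of the mixed cluster and genes of classes found mainly with LPS were chosen after their values were seen.

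RNA free in the droplets was estimated per gene and library as the 25th percentile, over sub-clusters of at least 10 cells, of the mean UMIs per barcode. The estimate assumes that some sub-cluster does not express the gene. Against a group at 0 a fold was computed from a floor of 3 UMIs over the group. Intervals and floors cover counting error only.

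Each alternative changed 1 choice, except 1 added later that changed the makeup of the phagocyte-like class and the minimum of UMIs per cell together. Those fixed beforehand were RLE size factors, DESeq2 1.42.0, limma-voom, no filter on low counts, sums thinned to equal UMIs, a looser cell filter (200 genes, 25% mitochondrial) and a stricter one (1000 UMIs, 500 genes, 10%), doublets kept, clustering resolutions 0.5 and 2.0, classes from each cell's own markers, and leaving out each control. Alternatives chosen after seeing the data were free RNA subtracted, leaving out Gm42418, AY036118, Lars2, haemoglobin and mitochondrial genes, removing the top 5% of doublet scores, cells with at least 1000 UMIs outside those genes, the first naming rule, and 4 other makeups of the phagocyte-like class.

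The edgeR step was tested on simulated data for each class, with 200 genes changed by known folds, 50 per fold. In endothelial-like cells (8571 genes) it recovered 0%, 70%, 84% and 94% of genes changed 2-, 4-, 8- and 16-fold, and called 1 unchanged gene. For phagocyte-like cells (8199 genes) it recovered 0%, 42%, 72% and 80%, with 10 unchanged genes called. Fibroblast-like cells (5359 genes) gave 4%, 48%, 80% and 84%, with 11 called, and lymphoid-like cells (9703 genes) 0%, 0%, 30% and 56%, with 1 called. So 2-fold changes were nearly out of reach at this depth and replication. False calls in the real libraries were not tested. Gene coordinates were matched by Ensembl identifier. Erythroid-like, unnamed and near-empty barcodes and classes under 20 cells were left out of the tests. Further tools were Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, anndata 0.12.19, igraph 0.11.9, matplotlib 3.10.9 and R 4.3.3.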

Results

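Single-cell RNA was measured with 10x 3' droplet chemistry in cells from the intima, the inner lining, of the lesser curvature of the mouse aortic arch. The C57BL/6J mice were 12 to 13 weeks old, and each library pooled cells of 5 to 10 animals of both sexes. The series title names sphingosine-1-phosphate (S1P), a signalling lipid of blood plasma, and the return of intimal myeloid cells across the endothelium. Groups compared were 2 libraries of untreated control mice and 1 library of mice given 30 µg of lipopolysaccharide (LPS), a bacterial product sensed by Toll-like receptor 4, intravenously 18 h before harvest. Control replicate 1 held 1269 barcodes and 4940996 unique molecular identifiers (UMIs, 1 per captured RNA molecule), control replicate 2 held 4813 barcodes and 20069697 UMIs, and the LPS library held 6000 barcodes and 21864072 UMIs. Median UMIs per barcode were 1572, 3267 and 2032 in that order, and median genes per barcode were 304, 1343 and 518.

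The libraries also differed in RNA quality. Gm42418, a ribosomal RNA-like transcript, took 9.81% of the UMIs of control replicate 1, 1.59% of control replicate 2 and 28.6% of the LPS library, and haemoglobin transcripts took 44.0%, 7.91% and 25.2%. After filtering, 431, 2697 and 5156 barcodes were kept. Of these, 2 (0.466%), 0 (0%) and 3385 (65.7%) lay in unnamed, near-empty clusters with at least 40% Gm42418, where the LPS barcodes had a median of 1895 UMIs over 516 genes and smooth muscle genes such as Myh11 and Tagln among the leading genes. The doublet caller marked 6 of 8284 barcodes, too few to have worked, so doublets remained in the data. RNA free in the droplets, estimated per gene from the sub-clusters in which it was low, made up 18.3%, 33.1% and 16.5% of the endothelial-like UMIs and 47.6%, 53.8% and 50.6% of the phagocyte-like UMIs in control replicate 1, control replicate 2 and the LPS library.

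Cell classes were rebuilt here from marker genes, so names are given as likeness. Endothelial-like cells (49, 106 and 182 in control replicate 1, control replicate 2 and the LPS library), mononuclear phagocyte-like cells (73, 202 and 330), fibroblast-like cells (25, 71 and 162) and T, NK or innate lymphoid-like cells (162, 1677 and 104) had at least 20 cells in every library and were tested. As shares of the 361, 2153 and 941 named cells other than erythroid-like ones, with exact Clopper-Pearson 95% intervals that cover counting error only, endothelial-like cells made up 13.6% (10.2 to 17.5), 4.92% (4.05 to 5.92) and 19.3% (16.9 to 22.01). Phagocyte-like cells took 20.2% (16.2 to 24.7), 9.38% (8.18 to 10.7) and 35.1% (32.0 to 38.2), and fibroblast-like cells 6.93% (4.53 to 10.1), 3.30% (2.58 to 4.14) and 17.2% (14.9 to 19.8). Lymphoid-like cells made up 44.9% (39.7 to 50.2), 77.9% (76.1 to 79.6) and 11.1% (9.12 to 13.2). Shares can be set by dissection and by barcode selection, the controls themselves lay apart, and 2 libraries against 1 cannot go below an exact permutation p of 0.333, so no share was tested. Neutrophil-like cells took 0.831% (0.172 to 2.41), 0.0464% (0.00118 to 0.259) and 3.72% (2.60 to 5.14). Smaller classes were mesothelial-like (2, 0 and 47 cells), B-like (6, 16 and 19), smooth muscle-like (33, 0 and 0), pericyte-like (0, 62 and 0), adipocyte-like (0, 12 and 26) and erythroid-like cells (4, 385 and 794). Counts of 0 allow shares of named cells of up to 0.831% in control replicate 1 (pericyte- and adipocyte-like), 0.139% in control replicate 2 (mesothelial- and smooth muscle-like) and 0.319% in the LPS library (smooth muscle- and pericyte-like), taken as 3 cells over those named. Unnamed barcodes are outside these limits, and some in every library had leading genes of smooth muscle- or pericyte-like cells, so those classes are not bounded. Unnamed barcodes made up 14.9%, 5.76% and 66.3% of those kept.

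The first comparison asks which genes of the vessel lining differed 18 h after LPS. In endothelial-like cells, Lcn2, which encodes an iron-siderophore-binding protein, went from 0 and 1 UMIs in the controls to 21614 with LPS, 11240.1-fold (2017 to 443980) higher with its 95% counting interval (log2 fold change 13.29 ± 0.57 SE, adjusted p = 1.05e-112). Cxcl10 and Cxcl9, ligands of the chemokine receptor Cxcr3, and Csf3, the granulocyte growth factor G-CSF, had no UMI in either control and were at least 235-fold, at least 167-fold and at least 192-fold higher. Selp, the leukocyte-tethering selectin of activated endothelium, rose by 3.65 ± 0.36 on the log2 scale (adjusted p = 6.65e-21), and Icam1, a ligand of leukocyte integrins, by 2.85 ± 0.38 (adjusted p = 4.81e-12). Genes that fell included Dbp, an output gene of the circadian clock, from 349 and 327 CPM (UMIs scaled for library size) to 4.31 (log2 fold change -6.24 ± 0.61, adjusted p = 1.66e-21), and Sfrp2, a secreted Wnt modulator, 223-fold (39.3 to 8885) lower.

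In all, 690 of 8571 genes tested were higher and 628 lower with LPS at an adjusted p under 0.05 (edgeR quasi-likelihood test, 2 control libraries against 1), and in 1305 of these the LPS value lay outside both controls. From here on, a value after a gene is the fitted log2 fold change ± SE. A fold with "at least" is a bound against a floor of 3 UMIs over the group at 0, and a fold with a range is a ratio with its 95% counting interval, for genes with 1 to 3 UMIs in one group. Adamts4, a proteoglycan-cleaving protease (at least 32.6-fold), Car4, a carbonic anhydrase (at least 32.4-fold), Serpina3f (at least 28.6-fold) and the cytokine Il6 (at least 23.6-fold) were among the most increased genes. Others were Tmem252 (583-fold, 105 to 23067), AA467197 (305-fold, 54.6 to 12078), the monocyte chemokine Ccl2 (692-fold, 124 to 27339) and Saa3 (at least 31.03-fold), whose 179 LPS UMIs were no more than free RNA would give. The most decreased genes were Otogl (at least 23.7-fold), Nppc (at least 12.8-fold), which encodes C-type natriuretic peptide, Ret (at least 11.5-fold), the Wnt ligand Wnt9b (108-fold, 18.6 to 4328) and the Wnt inhibitor Sost (145-fold, 48.9 to 708). They were followed by Tcap (131-fold, 22.7 to 5239.7), G0s2 (98.1-fold, 16.8 to 3949), Tppp3 (56.7-fold, 15.02 to 479), the clock repressor Bhlhe41 (61.5-fold, 10.3 to 2505) and Gap43 (48.1-fold, 7.87 to 1974). The time of day at harvest, which bears on clock genes such as Dbp and Bhlhe41, is not given in the sources used here. Controls were far apart for Wnt9b (221 and 17.1 CPM, against 0.615 with LPS) and Sost (14.8 and 347 CPM, against 1.85). Sost is also among the smooth muscle markers used for naming, and Tcap was lower in phagocyte-like and fibroblast-like cells too. Neither decrease is thus shown to be particular to endothelial cells.

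On the GRCm38/mm10 assembly, whole gene bodies in GENCODE mouse release 21 place Lcn2 (ENSMUSG00000026822) from 32384633 to 32388252 on chromosome 2 and Cxcl10 (ENSMUSG00000034855) from 92346638 to 92348889 on chromosome 5. The adhesion genes are Selp (ENSMUSG00000026580) from 164115264 to 164150026 on chromosome 1 and Icam1 (ENSMUSG00000037405) from 21015985 to 21028817 on chromosome 9. The S1P genes are S1pr1 (ENSMUSG00000045092) from 115710433 to 115715072 on chromosome 3 and Sphk1 (ENSMUSG00000061878) from 116530925 to 116536674 on chromosome 11.

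**Figure D1:**
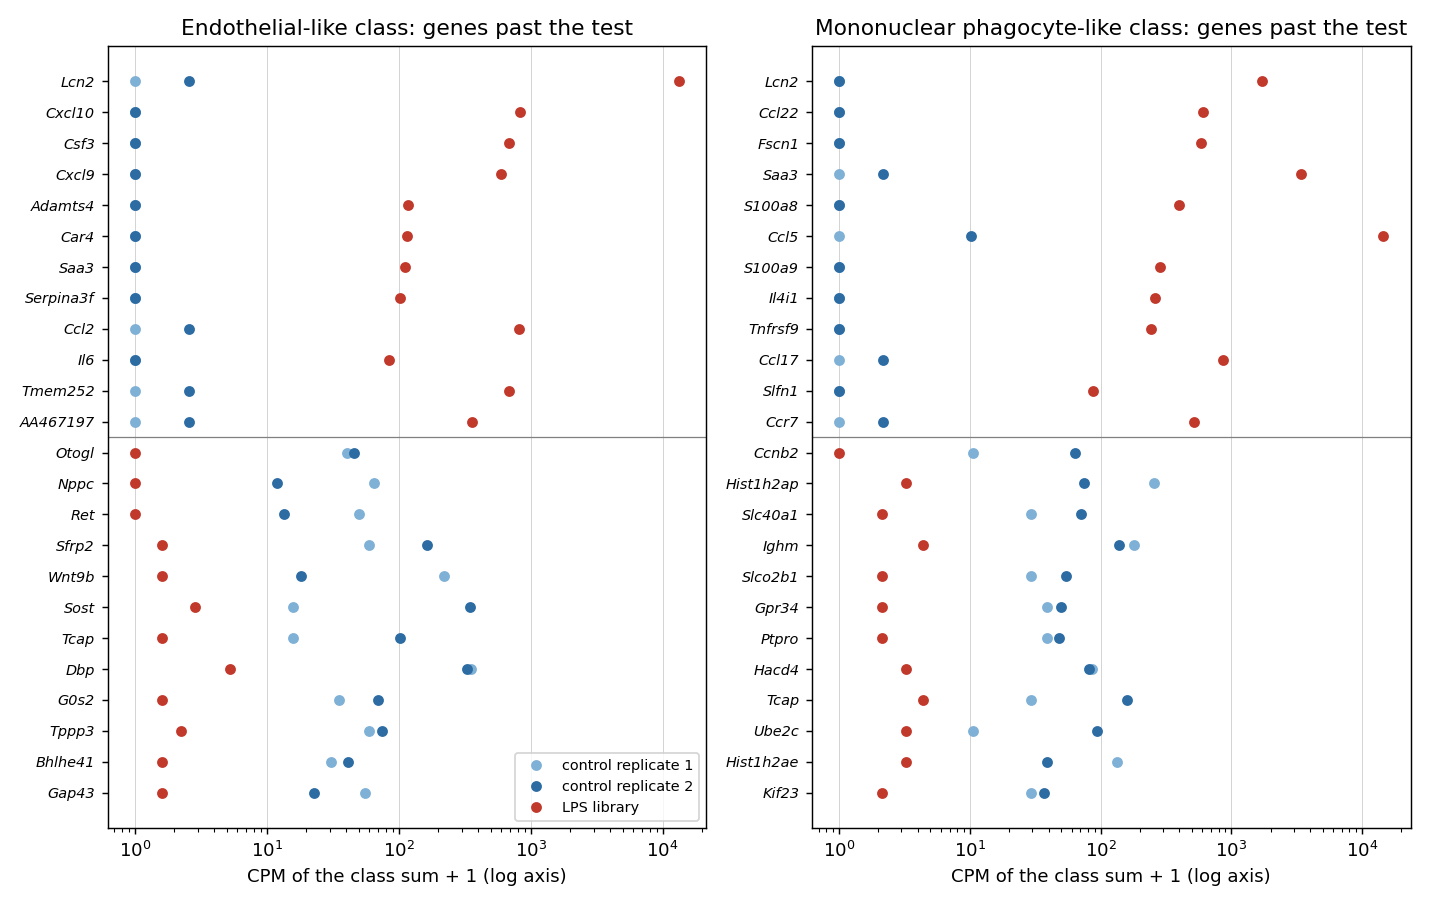
Scaled UMI level (CPM plus 1, log axis) of the most increased and most decreased genes in endothelial-like and phagocyte-like cells, with 1 point per library for control replicate 1 (light blue), control replicate 2 (dark blue) and the LPS library (red). Lcn2 sits at 0 and 1.56 CPM in the endothelial-like control sums and at 13303 CPM with LPS, and Dbp at 349, 327 and 4.31 CPM.

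Inflammatory lists held many of the increases in endothelial-like cells. Of acute-phase and LPS feedback genes, 28 of 29 measured genes rose and 1 did not pass (28 adjusted over the list alone, median log2 fold change 3.85, or 3.78 with genes at 0 set to their bound). Lcn2 and the metal-binding protein gene Mt2 (7.75 ± 0.44) were among them. Of guanylate-binding protein and GTPase genes, which act in defence inside cells, 14 of 15 measured genes rose and 1 did not pass (15 adjusted over the list alone, median log2 fold change 2.65). Among them were Gbp6 (3.76 ± 0.44), Gbp5 (3.35 ± 0.42) and Gbp2 (3.14 ± 0.39). Near-identical Gbp, Tgtp, Ifi20x, H2-Q and Hba-a copies can share reads, so single members are uncertain. In the type I interferon list 31 of 41 measured genes rose, 0 fell and 10 did not pass (33 higher and 1 lower adjusted over the list alone, median log2 fold change 2.00). The antiviral gene Rsad2 (5.70 ± 0.53), Zbp1 (4.74 ± 0.54) and the transcription factor gene Irf7 (4.57 ± 0.48) rose. Of NF-kB targets and cytokines, 15 of 21 measured genes rose and 6 did not pass (19 adjusted over the list alone, median log2 fold change 2.20). Among them were Csf3, Il6 and the prostaglandin synthase gene Ptgs2 (6.13 ± 0.56). Chemokines followed, as 8 of 13 measured genes rose and 5 did not pass (9 adjusted over the list alone, median log2 fold change 5.12, or 3.09 with genes at 0 set to their bound). They included Cxcl10, Cxcl9, Ccl2 and Ccl7 (at least 8.49-fold). The red cell and platelet list is not an inflammatory one, and 5 of 5 measured genes rose and 0 did not pass (5 adjusted over the list alone, median log2 fold change 3.81). Among them were Hbb-bs (3.81 ± 0.38) and the platelet integrin gene Itga2b (13.3-fold, 3.49 to 112). Haemoglobin shares of whole libraries are given above. Without control replicate 1, Ptgs2 had a log2 difference of 5.41. Without control replicate 2, Ptgs2 and Rsad2 had a log2 difference of 7.56 and 4.68, in order. All upward as sets, these lists had camera adjusted p = 8.33e-35, 3.19e-23, 3.19e-16, 6.85e-17, 6.49e-09 and 1.36e-21 at a preset correlation, in order. They had adjusted p = 0.325 for each with an estimated correlation.

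Adhesion genes went both ways. In that list 5 of 23 measured genes rose, 2 fell and 16 did not pass (7 higher and 3 lower adjusted over the list alone, median log2 fold change 0.11). Selp, Sele (3.03 ± 0.43), Icam1 and the connexin gene Gja1 (2.05 ± 0.46) rose. Vcam1, another leukocyte adhesion gene, stood at 1831, 1663 and 3039.8 CPM in control replicate 1, control replicate 2 and LPS and did not pass (log2 fold change 0.80 ± 0.34, adjusted p = 0.0964). Of MHC class I genes, 4 of 22 measured genes rose and 18 did not pass (4 adjusted over the list alone, median log2 fold change 0.37). Among them were the peptide transporter gene Tap1 (2.21 ± 0.42) and Tapbp (1.79 ± 0.38). Of MHC class II genes, 0 of 7 measured genes rose and 7 did not pass (0 adjusted over the list alone, median log2 fold change 0.12), with Cd74 at 0.65 ± 0.37 and H2-Aa at 0.12 ± 0.40. In the dendritic maturation list 5 of 12 measured genes rose, 0 fell and 7 did not pass (5 higher and 1 lower adjusted over the list alone, median log2 fold change 0.96). Ccl5 (112-fold, 19.9 to 4457), the checkpoint ligand gene Cd274 (3.90 ± 0.54), Birc2 (2.99 ± 0.41) and Cd200 (1.73 ± 0.37) rose and are not specific to dendritic cells. Immediate-early genes gave a mixed count, as 8 of 25 measured genes rose, 1 fell and 16 did not pass (8 higher and 2 lower adjusted over the list alone, median log2 fold change 0.60). Fosb (14.9-fold, 4.93 to 73.7) and Atf3 (3.04 ± 0.60) rose. In the complement list 5 of 13 measured genes rose, 0 fell and 8 did not pass (5 higher and 3 lower adjusted over the list alone, median log2 fold change 0.24). Cfb (5.83 ± 0.59) and Serping1 (2.91 ± 0.41) rose. Coagulation genes split, as 3 of 16 measured genes rose, 3 fell and 10 did not pass (3 higher and 4 lower adjusted over the list alone, median log2 fold change -0.68). The factor VIII gene F8 (-2.88 ± 0.90) fell. With control replicate 1 left out, Gja1, Cd274, Fosb, Atf3, Cfb and F8 had a log2 difference of 2.95, 5.36, 3.06, 3.70, 5.07 and -2.08, in order. With control replicate 2 left out, Gja1, Cd274, Fosb, Atf3 and Cfb had a log2 difference of 0.82, 2.07, 4.65, 1.51 and 6.96, in order. Upward as sets, these lists up to complement had camera adjusted p = 0.0334, 7.80e-04, 0.644, 0.00159, 0.0136 and 0.187 at a preset correlation, in order. In the same order they had adjusted p = 0.449, 0.429, 0.809, 0.429, 0.429 and 0.798 with an estimated correlation. Coagulation had a camera adjusted p = 0.777, downward.

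Vessel wall lists held more decreases. Of endothelial identity and flow-responsive genes, 3 of 44 measured genes rose, 16 fell and 25 did not pass (3 higher and 17 lower adjusted over the list alone, median log2 fold change -0.68). Cytl1 (-3.26 ± 0.41) and the growth factor gene Bmp6 (-3.18 ± 0.46) fell and Hmox1 (2.68 ± 0.90) and Adm (2.62 ± 0.62) rose. Klf2, a flow-induced transcription factor gene, stood at 704, 676 and 601 CPM and did not pass (adjusted p = 0.803). In the matrix and contractile list 4 of 33 measured genes rose, 14 fell and 15 did not pass (4 higher and 18 lower adjusted over the list alone, median log2 fold change -1.19). Fbln5 (-4.29 ± 0.50), Cnn1 (-3.27 ± 0.53) and Myl9 (-3.16 ± 0.48) fell and Timp1 (3.16 ± 0.45) rose. Free RNA would give 40% of the LPS UMIs of Cnn1 and 72.2% of those of Myl9, smooth muscle transcripts, and a smooth muscle-like class was found in control replicate 1 alone. With free RNA subtracted, 8 of the 14 genes that fell still passed. Of endothelial-to-mesenchymal genes, 1 of 14 measured genes rose, 6 fell and 7 did not pass (1 higher and 7 lower adjusted over the list alone, median log2 fold change -0.96). Acta2 (-2.70 ± 0.44), S100a4 (-2.22 ± 0.50) and Vim (-2.19 ± 0.39) fell. Acta2 had 22, 1065 and 228 UMIs and S100a4 1, 62 and 22 UMIs in control replicate 1, control replicate 2 and LPS, and without control replicate 2 their log2 differences turned to 0.31 and 1.10. Without control replicate 1, Hmox1, Adm and Myl9 had a log2 difference of 1.97, 2.00 and -3.86, in order. Without control replicate 2, Hmox1, Adm, Cnn1 and Myl9 had a log2 difference of 3.88, 4.57, -1.16 and -0.38, in order. Downward as sets, these lists had camera adjusted p = 1.48e-07, 1.28e-07 and 0.00287 at a preset correlation, in order. They had adjusted p = 0.325, 0.679 and 0.429 with an estimated correlation.

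Metabolic and remaining lists were mixed. Of hypoxia and oxidative stress genes, 6 of 21 measured genes rose, 3 fell and 12 did not pass (6 higher and 3 lower adjusted over the list alone, median log2 fold change 0.56). Sod2 (3.40 ± 0.41) and the cystine transporter gene Slc7a11 (at least 9.01-fold) rose. In glycolysis 4 of 16 measured genes rose, 0 fell and 12 did not pass (4 higher and 1 lower adjusted over the list alone, median log2 fold change 0.10). The glucose transporter gene Slc2a1 (2.76 ± 0.60) and Hif1a (2.44 ± 0.39) rose. In lipid handling 1 of 22 measured genes rose, 2 fell and 19 did not pass (1 higher and 3 lower adjusted over the list alone, median log2 fold change -0.14). The fatty acid-binding protein gene Fabp4 (1.99 ± 0.37) rose and Fabp5 (-2.87 ± 0.48) and Apoe (-2.14 ± 0.37) fell. In the macrophage identity list 2 of 16 measured genes rose, 4 fell and 10 did not pass (2 higher and 5 lower adjusted over the list alone, median log2 fold change -0.88). Of these the hyaluronan receptor gene Lyve1 (5.50 ± 0.57) and the phagocytic receptor gene Mertk (2.04 ± 0.45) rose and Cbr2 (-2.24 ± 0.64) fell. In the cell cycle list, where median and set test differ in sign, 2 of 7 measured genes fell and 5 did not pass (2 adjusted over the list alone, median log2 fold change 0.46). These were Stmn1 (-2.76 ± 0.78), a microtubule regulator gene, and the histone variant gene H2afz (-1.56 ± 0.44). In leukocyte migration 1 of 15 measured genes rose and 14 did not pass (1 adjusted over the list alone, median log2 fold change 0.04), the 1 being the protease gene Mmp14 (1.83 ± 0.46). With control replicate 1 left out, Fabp4 had a log2 difference of 1.25. With control replicate 2 left out, Fabp4, Fabp5 and Lyve1 had a log2 difference of 3.88, -1.53 and 4.03, in order. Camera adjusted p values were 0.153, 0.496, 0.187, 0.0833, 0.514 and 0.656 in this order, none a call.

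Among S1P genes, a receptor and a kinase gene rose and an exporter gene fell in endothelial-like cells. S1pr1, the main endothelial S1P receptor, rose from 364 and 203 CPM to 838 (log2 fold change 1.61 ± 0.38, adjusted p = 4.25e-04), and free RNA would give 3.33% of its LPS UMIs. Against control replicate 1 alone the log2 difference was 1.14 and against control replicate 2 alone 2.01. In the receptor list 1 of 2 measured genes rose and 1 did not pass (1 adjusted over the list alone, median log2 fold change 0.68), too few for a set test. S1pr4 stood at 19.7, 10.9 and 11.7 CPM (adjusted p = 0.925). Sphk1, a kinase that makes S1P, rose from 9.84 and 9.35 CPM to 103 (log2 fold change 3.43 ± 0.53, adjusted p = 9.60e-09). Spns2, the S1P exporter of endothelial cells, fell from 19.7 and 32.7 CPM to 3.08 on 4, 21 and 5 UMIs (log2 fold change -3.13 ± 1.03, adjusted p = 0.0211). Its adjusted p ran from 0.00455 to 0.340 over the alternatives, without a pass at clustering resolution 0.5 (0.0950), with classes from each cell's own markers (0.340) or with the first naming rule (0.0659). Of S1P synthesis, transport and breakdown genes, 1 of 15 measured genes rose, 1 fell and 13 did not pass (1 higher and 2 lower adjusted over the list alone, median log2 fold change 0.00), with a camera adjusted p = 0.795. The Icam1 controls stood at 78.7 and 259 CPM against 1310 with LPS, log2 differences of 3.96 and 2.30 against each alone, and DESeq2 did not call it (adjusted p = 0.264, over all alternatives 1.73e-27 to 0.264).

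Sub-clusters of the class, chosen after the data were seen, held either control or LPS cells, so kinds of cell and effects of LPS are not separated. One led by Vcam1 and Vwf held 14 cells of control replicate 1 and 49 of control replicate 2, with 68.8% and 74.7% of their UMIs in the class. Another led by Ephx2 and Edn1 held 34 of control replicate 1 (23.8% of UMIs), and one led by Cdh11 and Ctla2a 57 of control replicate 2 (25.3%). The LPS cells split into 73 led by Tmem252, Ramp2, Ccl2 and Selp (70.1% of UMIs) and 109 led by Kcnq1ot1 and Gbp4. Clustering in 1 step put no control cell in the class, DESeq2 called 146 genes higher and 156 lower, and Gm42418 took 13.2%, 1.80% and 12.6% of its UMIs.

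The second comparison concerns the myeloid cells of the title. In mononuclear phagocyte-like cells, Ccl5, a chemokine that draws T cells and monocytes, went from 0 and 9.25 CPM in the controls to 14564 with LPS (log2 fold change 10.85 ± 1.04, adjusted p = 5.14e-22). Genes of mature migratory dendritic cells rose with it. The lymph node homing receptor gene Ccr7 was 504-fold (89.9 to 19934) higher (adjusted p = 9.87e-19), the actin-bundling gene Fscn1 at least 189.9-fold and the chemokine gene Ccl22 at least 197-fold. A sub-cluster of 7 dendritic-like LPS cells held 464 of the 465 Ccr7 UMIs, 509 of 526 for Fscn1, 509 of 545 for Ccl22, 225 of 231 for Il4i1, 207 of 216 for Tnfrsf9, 663 of 780 for Ccl17 and 2157 of 13048 for Ccl5. The fractalkine receptor gene Cx3cr1 fell, with 22, 274 and 13 UMIs in control replicate 1, control replicate 2 and LPS (log2 fold change -4.20 ± 0.73, adjusted p = 1.12e-06), as did Slc40a1, the iron exporter ferroportin, 59.1-fold (10.2 to 2370.0) lower (adjusted p = 1.90e-05).

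Of 8199 genes tested, 357 were higher and 125 lower, and for 468 of these the LPS value lay outside both controls. The most increased genes also held Saa3 (3341-fold, 599 to 132013), an acute-phase protein gene, and the calprotectin genes S100a8 (at least 129-fold) and S100a9 (at least 91.3-fold). Next came Il4i1 (at least 83.4-fold), the costimulatory receptor gene Tnfrsf9 (at least 78.0-fold), Ccl17 (845-fold, 151 to 33409), Slfn1 (at least 27.8-fold) and Lcn2 (at least 559.9-fold), with 66.6% of its LPS UMIs expected from free RNA. The most decreased genes were the mitotic genes Ccnb2 (at least 16.9-fold), Ube2c (37.4-fold, 10.0 to 314) and Kif23 (31.4-fold, 5.27 to 1276), and the histone genes Hist1h2ap (42.0-fold, 11.3 to 352) and Hist1h2ae (21.7-fold, 5.68 to 184), which have near-identical copies and are uncertain. Also lower were the immunoglobulin gene Ighm (42.2-fold, 14.1 to 207), Slco2b1 (45.2-fold, 7.75 to 1823), Gpr34 (42.5-fold, 7.25 to 1714), Ptpro (41.5-fold, 7.09 to 1677), Hacd4 (36.5-fold, 9.77 to 306) and Tcap (43.4-fold, 14.5 to 213). Ube2c (1 and 80 UMIs) and Tcap (3 and 138) rested mostly on control replicate 2.

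In the same annotation are Ccl5 (ENSMUSG00000035042) from 83525778 to 83530518 on chromosome 11 and Ccr7 (ENSMUSG00000037944) from 99144196 to 99155077 on chromosome 11.

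Of dendritic maturation genes, 18 of 21 measured genes rose and 3 did not pass (19 adjusted over the list alone, median log2 fold change 3.68, or 3.53 with genes at 0 set to their bound). Among them were Ccl22, Fscn1, Ccl5 and Ccl17. Without the 7 dendritic-like cells Fscn1 no longer passed (adjusted p = 0.0695, over all alternatives 3.90e-24 to 0.0814). Of type I interferon genes, 32 of 47 measured genes rose and 15 did not pass (39 adjusted over the list alone, median log2 fold change 2.56). Among them were Irf7 (6.64 ± 0.75), Oasl1 (112-fold, 19.6 to 4448) and Ms4a4c (107-fold, 29.1 to 887). In the acute-phase list 24 of 32 measured genes rose and 8 did not pass (26 adjusted over the list alone, median log2 fold change 3.55, or 3.31 with genes at 0 set to their bound). Saa3, Lcn2, Lrg1 (at least 12.6-fold) and Ifitm1 (at least 11.9-fold) rose. In the NF-kB list 18 of 28 measured genes rose and 10 did not pass (21 adjusted over the list alone, median log2 fold change 2.31). The itaconate-producing enzyme gene Acod1 (at least 18.1-fold) and Tnfrsf9 rose. Free RNA would give 72.4% of the LPS UMIs of Csf3 (at least 17.7-fold) and 71.7% of those of Il6 (at least 12.6-fold). In the guanylate-binding list 10 of 14 measured genes rose and 4 did not pass (12 adjusted over the list alone, median log2 fold change 3.18). Their expected free RNA was 57.6% for Gbp5 (5.13 ± 0.68), 92.5% for Iigp1 (4.58 ± 0.64) and 86.5% for Gbp2 (4.10 ± 0.60). Of chemokines, 9 of 21 measured genes rose, 1 fell and 11 did not pass (12 higher and 1 lower adjusted over the list alone, median log2 fold change 1.82). Cxcl3 (at least 7.58-fold) rose beside Ccl22, Ccl5 and Ccl17. Of MHC class I genes, 7 of 22 measured genes rose and 15 did not pass (10 adjusted over the list alone, median log2 fold change 1.47). Among them were H2-Q7 (2.59 ± 0.58) and Tapbp (2.39 ± 0.56). Against control replicate 1 alone, Irf7, Gbp5, Iigp1, Gbp2 and Tapbp had a log2 difference of 5.51, 6.15, 6.59, 5.49 and 3.15, in order. All upward as sets, these lists had camera adjusted p = 7.43e-17, 2.26e-26, 1.22e-18, 2.63e-14, 3.37e-11, 2.83e-05 and 4.28e-09 at a preset correlation, in order. In the same order they had adjusted p = 0.491, 0.491, 0.491, 0.491, 0.606, 0.491 and 0.491 with an estimated correlation.

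Lists of resident cell identity had few calls, in both directions. In MHC class II 1 of 11 measured genes rose, 1 fell and 9 did not pass (1 higher and 1 lower adjusted over the list alone, median log2 fold change -1.41). The class II transactivator gene Ciita (-3.12 ± 0.67) fell and the lysosomal thiol reductase gene Ifi30 (1.75 ± 0.57) rose. Of resident macrophage genes, 2 of 31 measured genes rose, 5 fell and 24 did not pass (3 higher and 12 lower adjusted over the list alone, median log2 fold change -1.01). Cx3cr1 and the growth factor gene Igf1 (-3.87 ± 0.73) fell and Timd4 (37.9-fold, 6.37 to 1539) and Lyve1 (21.1-fold, 5.47 to 181) rose. Of cell cycle genes, 8 of 29 measured genes fell and 21 did not pass (13 adjusted over the list alone, median log2 fold change -1.69). Ccnb2, Ube2c, Ccna2 (34.2-fold, 5.76 to 1385) and Cenpa (-3.21 ± 0.83) fell. Sub-clusters of cycling lymphoid-like cells, led by genes such as Mki67 and Ube2c, lay mostly in control replicate 2, where that class made up 77.9% of named cells. Downward as sets, these lists had camera adjusted p = 5.42e-04, 2.96e-05 and 2.45e-08 at a preset correlation, in order. They had adjusted p = 0.491, 0.491 and 0.606 with an estimated correlation. In leukocyte migration 4 of 33 measured genes rose, 3 fell and 26 did not pass (5 higher and 3 lower adjusted over the list alone, median log2 fold change -0.38). Ccr7 and the integrin gene Itgam (3.67 ± 0.62) rose and Cx3cr1 and the elastase gene Mmp12 (-2.99 ± 0.71) fell. In lipid handling 3 of 27 measured genes rose, 3 fell and 21 did not pass (6 higher and 6 lower adjusted over the list alone, median log2 fold change -0.10). Fabp4 (2.44 ± 0.55) rose and Apoe (-2.63 ± 0.88) and the lysosomal lipase gene Lipa (-2.36 ± 0.63) fell. Without control replicate 1, Ciita had a log2 difference of -2.50. Without control replicate 2, Mmp12, Fabp4, Fabp5 and Lipa had a log2 difference of -2.09, 4.85, 5.15 and -1.73, in order. Their camera adjusted p values were 0.145 and 0.936. Fabp5 rose (4, 107 and 1446 UMIs, 4.12 ± 0.62), and without the dendritic-like cells its log2 difference was -0.46.

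Vessel wall lists had few called genes, and free RNA would give large parts of several. In adhesion 2 of 22 measured genes rose, 1 fell and 19 did not pass (3 higher and 2 lower adjusted over the list alone, median log2 fold change 0.67). Selp (4.12 ± 0.63) rose, at 100% expected free RNA, and Mcam passed as lower on 0, 63 and 0 UMIs, with none in control replicate 1 either. Of endothelial identity genes, 3 of 41 measured genes rose, 1 fell and 37 did not pass (3 higher and 2 lower adjusted over the list alone, median log2 fold change -0.46). Adm (33.0-fold, 8.76 to 279) and the endothelin gene Edn1 (3.54 ± 0.60) rose and Cytl1 (-2.06 ± 0.62) fell. In complement 5 of 15 measured genes rose and 10 did not pass (5 adjusted over the list alone, median log2 fold change 0.28). Cfb (5.51 ± 0.73), Itgam and C3 (3.16 ± 0.59) rose. In coagulation 2 of 13 measured genes rose and 11 did not pass (3 adjusted over the list alone, median log2 fold change 0.86). Plat (2.25 ± 0.75) rose. Of matrix and contractile genes, 4 of 34 measured genes rose, 5 fell and 25 did not pass (7 higher and 6 lower adjusted over the list alone, median log2 fold change -0.13). Timp1 (4.25 ± 0.71) rose and Fbln5 (-3.33 ± 0.70) and Cnn1 (-2.36 ± 0.62) fell. In the endothelial-to-mesenchymal list 2 of 13 measured genes rose, 1 fell and 10 did not pass (3 higher and 3 lower adjusted over the list alone, median log2 fold change -0.11). S100a4 (2.29 ± 0.56) rose and Acta2 (-2.08 ± 0.69) fell. Against control replicate 2 alone, Cfb had a log2 difference of 4.80. Against control replicate 1 alone, Plat and Timp1 had a log2 difference of 3.78 and 3.15, in order. Camera adjusted p values of these lists were 0.130, 0.178, 0.157, 0.428, 0.936 and 0.936 in order, none a call. Without control replicate 2 the log2 differences of Acta2 (18, 1888 and 255 UMIs), Cnn1 and Cytl1 turned to 0.60, 0.26 and 0.01, and free RNA would give 82.5%, 41.0% and 74.0% of their LPS UMIs. S100a4 (2, 64 and 253 UMIs) turned to -1.03 without the dendritic-like cells.

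Stress and metabolic lists had few called genes as well. In the immediate-early list 1 of 24 measured genes rose and 23 did not pass (2 adjusted over the list alone, median log2 fold change 0.02), the 1 being the heat shock gene Hspb1 (1.77 ± 0.54). In glycolysis 2 of 17 measured genes rose, 0 fell and 15 did not pass (2 higher and 1 lower adjusted over the list alone, median log2 fold change 0.12). The phosphofructokinase activator gene Pfkfb3 (3.04 ± 0.59) and Hif1a (2.09 ± 0.57) rose. In hypoxia and oxidative stress 2 of 25 measured genes rose and 23 did not pass (4 adjusted over the list alone, median log2 fold change 0.23). Sod2 (2.68 ± 0.58) rose. Of red cell and platelet genes, 3 of 5 measured genes rose, 0 fell and 2 did not pass (4 higher and 1 lower adjusted over the list alone, median log2 fold change 1.86). Hba-a2 (2.32 ± 0.59) and Hbb-bs (1.86 ± 0.60) rose. Free RNA would give 82.6% of the Hbb-bs UMIs with LPS. Of S1P synthesis, transport and breakdown genes, 1 of 14 measured genes rose and 13 did not pass (1 adjusted over the list alone, median log2 fold change -0.05). Without control replicate 1, Hba-a2 and Hbb-bs had a log2 difference of 3.75 and 2.96, in order. Without control replicate 2, Hspb1, Sod2, Hba-a2 and Hbb-bs had a log2 difference of 5.28, 2.05, 1.10 and 1.01, in order. Camera adjusted p values were 0.936, 0.460, 0.501, 0.0742 and 0.936 in order, none a call. Sphk1, the gene that rose in the last list, had 0, 0 and 66 UMIs, at least 23.8-fold higher (adjusted p = 6.49e-08), with 52 of them in the 7 dendritic-like cells.

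Of S1P receptors in phagocyte-like cells, 1 of 2 measured genes rose and 1 did not pass (1 adjusted over the list alone, median log2 fold change 0.12). S1pr1 had 2, 38 and 107 UMIs (log2 fold change 1.65 ± 0.55, adjusted p = 0.0473), free RNA would give 76.9% of its LPS UMIs, and with free RNA subtracted its log2 difference was -0.06. Most alternatives did not call it (adjusted p from 0.0171 to 1.00), and against control replicate 1 or 2 alone the log2 difference was 2.32 or 1.38. Icam1 passed (2.15 ± 0.56, adjusted p = 0.00378, over the alternatives 0.00265 to 0.964) with 89.0% expected free RNA, and turned to -0.72 once that was subtracted. Vcam1 (1.22 ± 0.55, adjusted p = 0.244, 72.4% expected free RNA, -0.41 after subtraction), Klf2 (-1.20 ± 0.59, adjusted p = 0.309), the integrin gene Itgal (-1.11 ± 0.63, adjusted p = 0.447), S1pr2 (-1.42 ± 1.53, adjusted p = 0.824) and the S1P lyase gene Sgpl1 (0.41 ± 0.66, adjusted p = 0.901) did not pass.

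Sub-clusters of the class differed by library, with 60 of 73 cells of control replicate 1 in one led by Aif1 and C1qb. Control replicate 2 had 105 of 202 in one led by Aif1 and H2-Eb1 (25.3% of its UMIs), 45 in one led by Lgals3 and C1qa (17.2%), 35 in one led by Rgs1 and Ms4a7 (25.2%) and 17 in one led by Mmp12 (32.2%). The LPS library had 188 (led by Ccl5 and Ms4a7) and 117 (led by H2-Eb1, Ccl5 and Cd74) of 330. Gm42418 took 19.96%, 1.62% and 28.8% of the UMIs of the class, and 48.3% in the sub-cluster of 188 LPS cells. With phagocytes of a mixed cluster and only cells of at least 1000 informative UMIs, edgeR called 0 genes. With free RNA subtracted 100 were higher and 18 lower, 66 and 13 of them among the main calls.

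**Figure D2:**
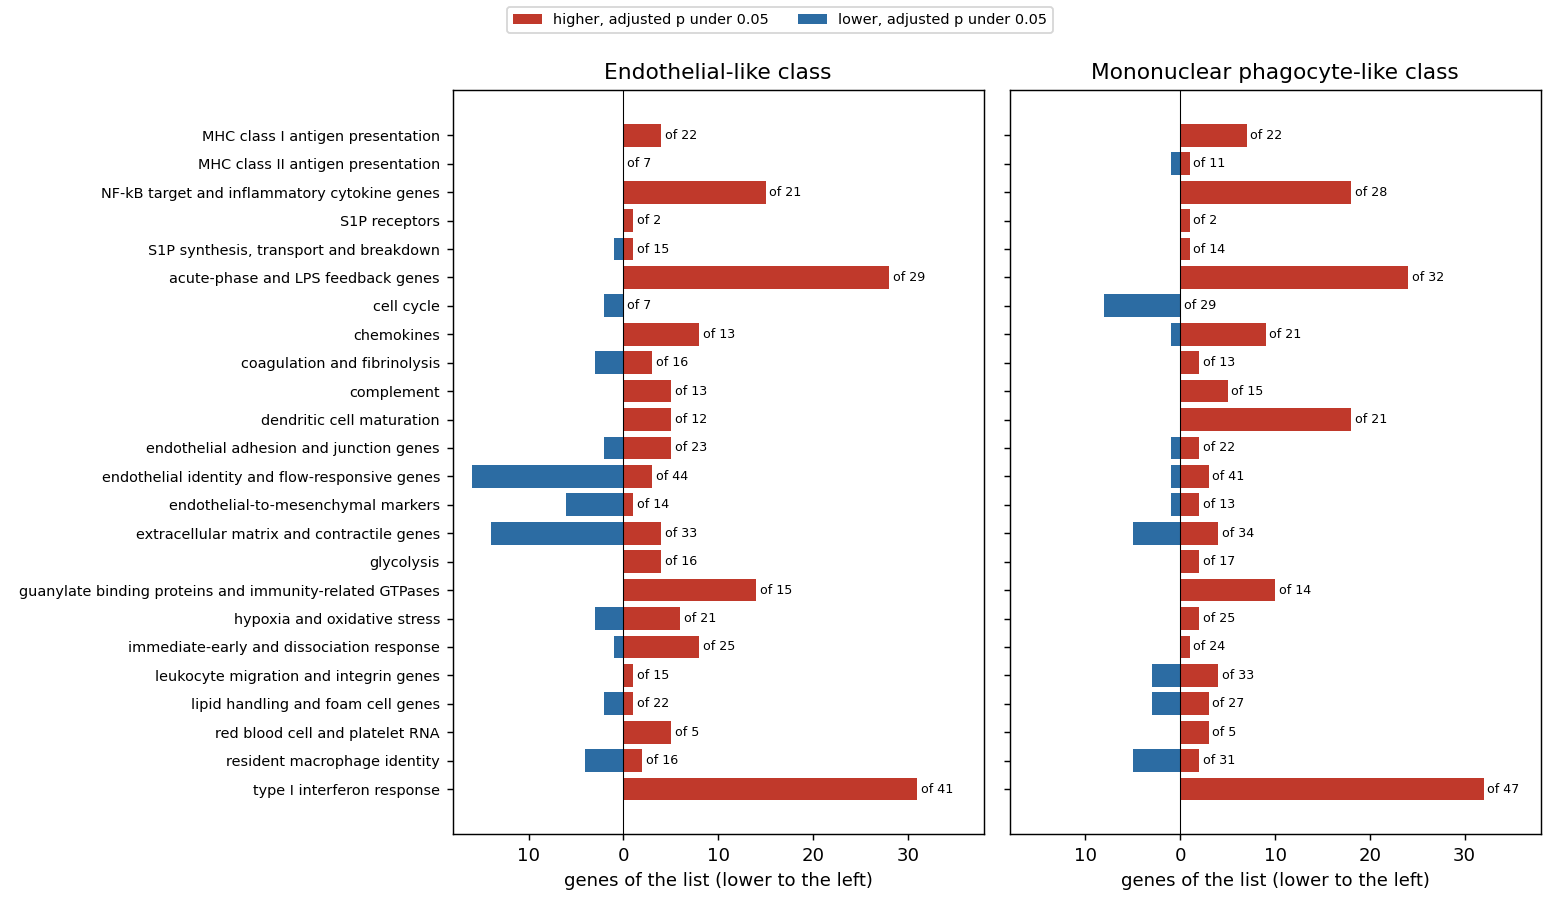
Number of genes of each fixed list that were higher (red, to the right) or lower (blue, to the left) with LPS at an adjusted p under 0.05, out of the number measured, in endothelial-like and phagocyte-like cells. Acute-phase genes were higher in 28 of 29 and 24 of 32, and dendritic maturation genes in 5 of 12 and 18 of 21.

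Whether both classes responded alike was tested within libraries as an interaction. The response differed for 73 of 9884 genes, 47 with a higher value in phagocyte-like cells and 26 in endothelial-like cells. Fabp5, a fatty acid-binding protein gene, had the log2 difference 7.10 ± 0.90, adjusted p = 2.42e-11, and S100a4, a calcium-binding protein gene, 4.62 ± 0.78, adjusted p = 4.08e-06. Both fell in endothelial-like cells, though S100a4 stood at 1.10 there without control replicate 2. Without the dendritic-like cells neither difference passed (adjusted p = 0.0794 and 0.883), and the phagocyte-like responses turned to -0.46 and -1.03. Ccl2 (-7.23 ± 1.36, adjusted p = 8.91e-05) and Fosb (-5.70 ± 1.05, adjusted p = 5.84e-05) had the higher value in endothelial-like cells. Edn1 (3.33 ± 0.79, adjusted p = 0.00715) and Tppp3 (5.14 ± 1.03, adjusted p = 3.40e-04) had the higher value in phagocyte-like cells, and Mcam passed too (-7.77 ± 1.73, adjusted p = 0.00254), on phagocyte-like UMIs of control replicate 2 alone. With free RNA subtracted 14 and 1 genes were called, 7 and 0 of them among the main calls, and without the dendritic-like cells 18 and 20, with 15 and 19 among them. Of the genes named here only Fabp5 still passed with free RNA subtracted (adjusted p = 0.00160). The others kept their direction at larger SE (adjusted p from 0.0641 to 0.695).

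Acute-phase and interferon genes were higher in fibroblast-like cells. Lcn2 was at least 624-fold, Ptx3, a soluble pattern recognition protein gene, at least 306-fold and Saa3 5767-fold (1035 to 227792) higher, with Cxcl9 (at least 65.4-fold) and Rsad2 (at least 34.9-fold). Ccl19, the Ccr7 ligand gene, rose from 120 and 72.5 CPM to 920 (log2 fold change 3.39 ± 0.49, adjusted p = 6.98e-10). Hacd4 (at least 11.2-fold), Akr1c18 (at least 11.2-fold), the collagen gene Col15a1 (45.0-fold, 11.9 to 380.4), the creatine kinase gene Ckb (61.0-fold, 16.3 to 513) and Tcap (57.8-fold, 9.74 to 2346) were lower. Of 5359 genes tested, 416 were higher and 266 lower.

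In this class, counts higher and lower of those measured, with counts adjusted over the list alone in parentheses, were 39 and 0 of 41 (39 and 0) for interferon genes. They were 12 and 0 of 13 (13 and 0) for guanylate-binding genes, 19 and 0 of 24 (20 and 0) for acute-phase genes, 13 and 0 of 18 (15 and 0) for NF-kB targets and 9 and 1 of 13 (11 and 1) for chemokines. Further lists had 10 and 0 of 18 (11 and 0) for MHC class I, 5 and 0 of 8 (6 and 0) for dendritic maturation, 6 and 1 of 19 (9 and 1) for immediate-early and 6 and 0 of 20 (6 and 0) for hypoxia genes. All upward as sets, these lists had camera adjusted p = 3.22e-17, 1.12e-07, 9.77e-15, 4.06e-07, 3.49e-05, 6.85e-06, 5.35e-04, 0.00742 and 0.0247 at a preset correlation, in order. In the same order they had adjusted p = 0.446, 0.446, 0.446, 0.446, 0.446, 0.446, 0.446, 0.615 and 0.463 with an estimated correlation. Among the dendritic maturation genes that rose were Cd274 (33.0-fold, 5.67 to 1328) and Birc2 (3.60 ± 0.57), neither specific to dendritic cells. Matrix and contractile genes, such as Col15a1, counted 5 and 14 of 34 (5 and 21), endothelial-to-mesenchymal genes, such as Vim (-2.08 ± 0.48), 0 and 4 of 13 (0 and 5), and coagulation genes, such as the tissue factor gene F3 (-3.21 ± 0.57), 0 and 4 of 10 (0 and 4). Endothelial identity genes counted 2 and 5 of 24 (2 and 6) and macrophage identity genes, such as Igf1 (-3.34 ± 0.58), 0 and 2 of 13 (0 and 3). Downward as sets, these lists had camera adjusted p = 3.95e-04, 0.00845, 0.00733, 0.0348 and 0.0198 at a preset correlation, in order. They had adjusted p = 0.446, 0.615, 0.446, 0.687 and 0.617 with an estimated correlation. Sphk1 (24.9-fold, 6.67 to 209) and the ceramidase gene Acer3 (2.26 ± 0.71) rose in the S1P synthesis list, 2 and 0 of 10 (2 and 1). Leukocyte migration counted 1 and 0 of 12 (2 and 0), adhesion 3 and 0 of 13 (3 and 2), lipid handling 4 and 1 of 18 (4 and 1), complement 1 and 1 of 12 (1 and 1) and glycolysis 3 and 0 of 14 (3 and 0). Their camera adjusted p values were 0.506, 0.741, 0.741, 0.741, 0.211 and 0.555. Lists too short for a set test were S1P receptors at 0 and 0 of 3 (0 and 0), MHC class II at 0 and 0 of 4 (0 and 4), cell cycle at 0 and 0 of 4 (0 and 0) and red cell RNA at 4 and 0 of 4 (4 and 0).

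Adhesion genes in fibroblast-like cells included Icam1 (3.62 ± 0.62) and Vcam1 (1.84 ± 0.47), and free RNA would give 57.1% and 48.2% of their LPS UMIs. S1pr1 (1.98 ± 0.86, adjusted p = 0.124, 100% expected free RNA), S1pr2 (-1.86 ± 0.98, adjusted p = 0.232), S1pr3 (-0.70 ± 0.90, adjusted p = 0.720), Sgpl1 (-0.47 ± 1.44, adjusted p = 0.904) and Klf2 (0.38 ± 0.46, adjusted p = 0.705) did not pass. The class rests on sub-clusters chosen after the data were seen, with 21 of 25 cells of control replicate 1 in one led by Lum and Nr2f2, 56 of 71 of control replicate 2 in one led by Pi16 and Igfbp5 and 129 of 162 of the LPS library in one led by Ccl19 and Apod. No other tool or alternative was run on its genes, Gm42418 took 18.7%, 1.81% and 22.1% of its UMIs, and free RNA made up 27.5%, 49.2% and 36.1%.

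Lymphoid-like cells had 32 genes higher and 0 lower of 9703 tested by edgeR, with 1355 at an unadjusted p under 0.05 and no other tool run on this class. The chemokine genes Cxcl10 (2214-fold, 389 to 88289) and Cxcl2 (6.67 ± 0.40) and the calcitonin gene Calca (483-fold, 158 to 2398) rose, while Lcn2 (at least 2001-fold) and Saa3 (8.13 ± 0.71) passed at levels that free RNA alone would give. No gene fell, and those with the largest decreases were Pbk, Asf1b and Samd1 with 1 LPS UMI each (adjusted p = 0.104, 0.104 and 0.105) and Nt5dc2 and Tcap with 0 (adjusted p = 0.0997 and 0.336). S1pr1 (1.90 ± 0.33, adjusted p = 0.125, 60.3% expected free RNA) and Ccr7 (2.57 ± 0.33, adjusted p = 0.0787) did not pass. Counted in the same way, interferon genes, such as Ifit3 (5.01 ± 0.46), gave 7 and 0 of 44 (39 and 0). Guanylate-binding genes gave 3 and 0 of 15 (13 and 0), acute-phase genes 3 and 0 of 25 (17 and 0), chemokines 3 and 0 of 9 (6 and 0), dendritic maturation genes, with Cd274 (3.71 ± 0.35), 1 and 0 of 13 (5 and 1) and NF-kB targets 0 and 0 of 20 (13 and 0). MHC class I gave 0 and 0 of 23 (12 and 0), leukocyte migration 0 and 0 of 33 (4 and 0), immediate-early genes 0 and 0 of 23 (6 and 0) and complement 0 and 0 of 11 (0 and 0). All upward as sets, these lists had camera adjusted p = 4.07e-46, 8.05e-18, 5.94e-18, 5.76e-08, 2.31e-07, 2.62e-15, 4.28e-15, 9.96e-04, 9.96e-04 and 0.0426 at a preset correlation, in order. In the same order they had adjusted p = 0.448, 0.448, 0.448, 0.448, 0.448, 0.529, 0.448, 0.448, 0.448 and 0.989 with an estimated correlation. Cell cycle genes gave 0 and 0 of 31 (0 and 16), downward, with a camera adjusted p = 3.94e-17 at a preset correlation and adjusted p = 0.721 with an estimated correlation. No gene of the other lists passed over all genes tested, and adjusted over the list alone they gave 1 higher of 2 S1P receptors, 2 of 21 adhesion, 1 of 8 MHC class II, 1 of 14 coagulation and 2 of 4 red cell genes. They gave 1 higher and 2 lower of 18 glycolysis genes, and 0 of 14 S1P synthesis, 18 macrophage identity, 24 lipid, 36 endothelial identity, 34 matrix, 13 endothelial-to-mesenchymal and 23 hypoxia genes. The smallest camera adjusted p among them was 0.119. Genes of developing thymocytes (Rag1, Cd4, Cd8b1) were among the leading genes of the sub-clusters that held most control cells of this class, and 70 of 104 LPS cells lay in a sub-cluster led by Glcci1, Trbc2 and Rag1. A further 30 lay in one led by Gzma and Gzmb, with 9 of 162 and 0 of 1677 control cells. Sub-clusters led by the cycling genes Hist1h2ap, Dtl, Ube2c, Cdc20 and Hist1h3c held 0, 7, 0, 0 and 9 cells of control replicate 1, 59, 63, 38, 19 and 0 of control replicate 2 and 0, 0, 1, 0 and 2 LPS cells.

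Where S1P genes were detected without treatment was read from the controls, as CPM of all UMIs of a class with exact Poisson 95% intervals for counting error and, at 0, the limit of 3 UMIs over the class, control replicate 1 first. S1pr1 stood at 357 (280.4 to 448) and 211 (177 to 251) in endothelial-like cells, 17.3 (2.10 to 62.5) and 53.1 (37.6 to 73.0) in phagocyte-like cells, 0 (up to 43.2) and 22.1 (8.11 to 48.1) in fibroblast-like cells and 20.4 (12.8 to 30.9) and 21.2 (18.4 to 24.3) in lymphoid-like cells. S1pr2 was highest in fibroblast-like cells at 101 (40.5 to 208) and 40.5 (20.2 to 72.5), against 0 (up to 14.5) and 3.25 (0.394 to 11.8) in endothelial-like cells. S1pr3 stood at 72.0 (23.4 to 168) and 36.8 (17.7 to 67.7) in fibroblast-like cells and 0 (up to 14.5) and 0 (up to 4.88) in endothelial-like cells. S1pr4 was at 22.2 (14.2 to 33.1) and 20.8 (18.0 to 23.9) in lymphoid-like cells and 19.3 (5.26 to 49.4) and 11.4 (4.58 to 23.5) in endothelial-like cells. Spns2 stood at 19.3 (5.26 to 49.4) and 34.2 (21.1 to 52.2) in endothelial-like cells, Sphk1 at 9.65 (1.17 to 34.9) and 9.76 (3.58 to 21.2) there and 0 (up to 26.0) and 0 (up to 4.196) in phagocyte-like cells, and Sgpl1 at 17.3 (2.10 to 62.5) and 40.6 (27.2 to 58.3) in phagocyte-like cells. With LPS, neutrophil-like cells held S1pr4 at 68.9 (45.0 to 101), and S1pr5 had at most 2 UMIs in any class. Part of these UMIs can be RNA free in the droplets, which in control replicate 2 would give 6.31% of those of S1pr1 in endothelial-like, 41.1% in phagocyte-like, 91.5% in fibroblast-like and 62.4% in lymphoid-like cells. There it would give 8.59% of S1pr2 in fibroblast-like and 70.6% in endothelial-like cells and 23.7% of Sgpl1 in phagocyte-like cells. For the other values listed the estimate was 0% in that library. In control replicate 1 it was 0% for all but Sgpl1 (8.30%).

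**Figure D3:**
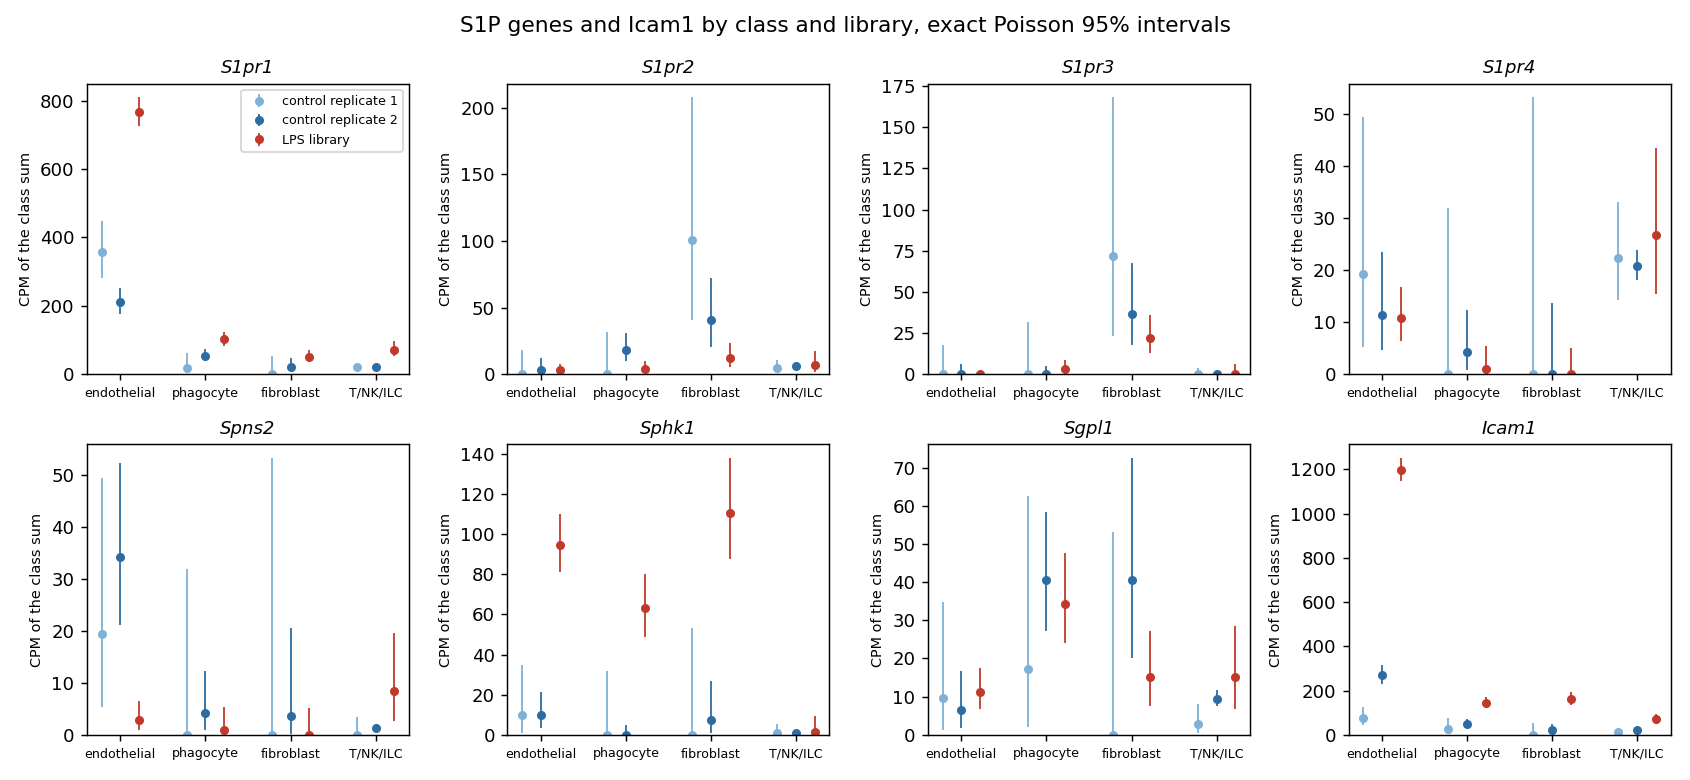
CPM of all class UMIs for 8 S1P-related genes (1 panel each, y axis) in endothelial-like, phagocyte-like, fibroblast-like and lymphoid-like cells, with 1 point per library and exact Poisson 95% intervals. S1pr1 stands highest in endothelial-like cells, at 357 and 211 CPM in the controls and 767 with LPS, and Spns2 there at 19.3, 34.2 and 2.82.

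Control spread sets the scale here. Across genes, not independent replicates, log2 CPM of the control sums had a Pearson correlation of 0.82 in endothelial-like, 0.71 in phagocyte-like, 0.66 in fibroblast-like and 0.88 in lymphoid-like cells. The LPS sum against each control gave 0.67 and 0.69, 0.58 and 0.70, 0.45 and 0.58, and 0.76 and 0.79 in order. Genes at a mean of at least 20 CPM whose controls were over 2-fold apart numbered 983 of 6645, 1580 of 5540, 1837 of 5288 and 437 of 6194. LPS lay over 2-fold from both in 1212, 875, 1231 and 859, fewer than these in phagocyte-like and fibroblast-like cells.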

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

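The comparison of both classes was designed beforehand, while the looks at near-empty barcodes, at phagocytes of a mixed cluster and without dendritic-like cells or free RNA were chosen only after the results were seen. Values in this part are log2 LPS responses of phagocyte-like minus endothelial-like cells ± SE, tested as an interaction (edgeR, adjusted p). The response differed for 73 of 9884 genes, and 709 genes had an unadjusted p under 0.05.

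Fabp5 differed by 7.10 ± 0.90 (adjusted p = 2.42e-11), with responses of 4.12 in phagocyte-like and -2.87 in endothelial-like cells. S100a4 differed by 4.62 ± 0.78 (adjusted p = 4.08e-06), with 2.29 and -2.22. Without the 7 dendritic-like cells these differences shrank to 2.56 ± 0.72 (adjusted p = 0.0794) and 1.35 ± 0.77 (adjusted p = 0.883) and the phagocyte-like responses turned to -0.46 and -1.03. In endothelial-like cells S100a4 turned to 1.10 without control replicate 2. Tppp3 differed by 5.14 ± 1.03 (adjusted p = 3.40e-04), with -0.48 and -5.62. Edn1 differed by 3.33 ± 0.79 (adjusted p = 0.00715), with 3.54 and 0.36. Fosb differed by -5.70 ± 1.05 (adjusted p = 5.84e-05), with -1.89 and 3.87. Ccl2 differed by -7.23 ± 1.36 (adjusted p = 8.91e-05), with 1.82 and 9.27. Mcam differed by -7.77 ± 1.73 (adjusted p = 0.00254), but had 0, 63 and 0 UMIs in phagocyte-like cells of control replicate 1, control replicate 2 and LPS, so this rests on 1 control library and is no measured size. With free RNA subtracted Fabp5 still passed (adjusted p = 0.00160), while S100a4, Tppp3, Edn1, Fosb, Ccl2 and Mcam did not (adjusted p = 0.0641, 0.116, 0.304, 0.0806, 0.0928 and 0.695). Their differences were then 7.44, 6.16, 4.81, -6.66, -8.21 and -6.30 in order, and their SE had risen to between 1.73 and 3.14.

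Unnamed near-empty barcodes (65.7% of those kept with LPS, 0.466% in control replicate 1, 0% in control replicate 2) entered no comparison. Named sub-clusters above the same cut of 40% Gm42418 were tested. They held 188 of 330 LPS phagocyte-like cells (48.3%) and 129 of 162 LPS fibroblast-like cells (40.4%). Phagocytes of a cluster that mixed classes also entered no main comparison, with 8, 6 and 36 cells in the controls and LPS. With LPS they held Arg1 at 723 CPM, Marco at 952 CPM and Cxcl13 at 3936.5 CPM, against 0 UMIs of each in the controls, at least 41.5-fold, 54.6-fold and 226-fold higher without a test. All 36 LPS cells lay in a sub-cluster named as macrophages and all but 1 of the control cells in another named as monocytes, so these folds also compare kinds of cell.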

How the results depend on the processing

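The interaction under other settings and the alternatives not fixed beforehand were chosen only after the results were seen. Over the alternatives with a test, the 99 named genes of endothelial-like cells gave 1329 values with the same call and direction. Of the others 111 were no longer past the threshold, 7 newly past it and 4 in the opposite direction. The 88 named genes of phagocyte-like cells gave 1222, 462, 0 and 12. Without control replicate 1, 91 of 91 called named genes kept their direction in endothelial-like and 83 of 83 in phagocyte-like cells. Without control replicate 2 these were 79 of 81 and 67 of 70. A single library against 1 has no test. Another scaling moved the median log2 fold change by under 0.1. Replicate numbers allowed no paired analysis. A stricter cell filter gave no endothelial-like test (12 cells in control replicate 1), nor did 1-step clustering (0 control cells). Causes were not tested, though thinning and stricter filters leave fewer UMIs by construction.

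Genes higher in endothelial-like cells (690) numbered 146 with DESeq2, 306 with thinned sums, 452 at resolution 0.5 and 453 at resolution 2.0. Genes lower (628) numbered 156 with DESeq2, 335 with thinned sums, 396 and 411 at these resolutions, 1066 with limma-voom and 998 with the first naming rule. Genes higher in phagocyte-like cells (357) numbered 214 with RLE size factors, 55 with DESeq2, 105 with thinned sums, 138 with the stricter filter, 99 with classes from each cell's own markers, 100 with free RNA subtracted and 187 in C1q-led sub-clusters only. Genes lower (125) numbered 43, 15, 26, 44, 23, 18 and 38 in the same order, and 79 with the looser filter. Of those, DESeq2 shared 146 and 156 with the main endothelial calls and 55 and 15 with the phagocyte calls, and free RNA subtraction 66 and 13. With phagocytes of the mixed cluster added and only cells of at least 1000 UMIs outside Gm42418, haemoglobin and mitochondrial genes, edgeR called 0 higher and 0 lower of 8938 (764 at an unadjusted p under 0.05). No other tool was run on those sums. Interaction calls of 47 and 26 became 14 and 1 with free RNA subtracted, and 18 and 20 without the dendritic sub-cluster. With an estimated correlation, camera called 0 lists up and 0 down in either class, which the single residual degree of freedom made nearly certain.

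Reversed values in endothelial-like cells were Acta2 at 0.31 and S100a4 at 1.10 without control replicate 2 (-3.58 and -2.72 without control replicate 1), Cd74 at -0.26 with classes from each cell's own markers, and H2-Aa at -0.10 with thinned sums, -0.84 with each cell's own markers and -1.01 with the first naming rule. In phagocyte-like cells Acta2 was at 0.60, Cnn1 at 0.26 and Cytl1 at 0.00807 without control replicate 2, and at -2.94, -2.85 and -2.71 without control replicate 1. With free RNA subtracted, Icam1 was at -0.72, Vcam1 at -0.41 and S1pr1 at -0.0644. Fabp5 was at -0.46 without the dendritic sub-cluster and -0.39 in C1q-led sub-clusters. S100a4 was at -0.73 with the stricter filter, -0.42 at resolution 2.0, -0.47 with each cell's own markers, -0.42 with mixed-cluster phagocytes added, -0.59 with these and at least 1000 UMIs, -1.03 without the dendritic sub-cluster and -0.89 in C1q-led sub-clusters.

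Shares of named cells moved out of their counting intervals as well. For endothelial-like cells control replicate 1 (13.6%) stood at 4.96% with the stricter filter, 6.07% at resolution 0.5, 17.6% at 2.0 and 21.2% without the top doublet scores. Control replicate 2 (4.92%) stood at 11.4% with the looser filter, 2.60% at resolution 0.5 and 3.58% with each cell's own markers. The LPS library (19.3%) stood at 25.3% with the looser filter, 9.81% with the stricter one, 15.2% with each cell's own markers and 12.6% with the first naming rule. For phagocyte-like cells control replicate 1 (20.2%) stood at 11.6% with the stricter filter, control replicate 2 (9.38%) at 13.5% and 7.21% with the looser and stricter filters, and the LPS library (35.1%) at 29.1% with the looser filter.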

Other observations

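The tests of dendritic maturation genes and of a whole-library offset of clock genes were chosen only after the results were seen, as were the genes named in this and the next paragraph. Phagocytes of the mixed cluster, led by Lyz2, Marco and Ly6c2 with LPS, differed from the other phagocyte-like cells in their genes. All but 1 control cell lay apart from the LPS cells, so kinds of cell and effects of LPS are not separated. In these cells, too few for a test, the siderophore-binding protein gene Lcn2 stood at 4301 CPM (at least 247-fold higher, with 0 control UMIs) and Ccl5 at 2234 CPM (at least 128-fold). Saa3 stood at 0, 297 and 26290 CPM in control replicate 1, control replicate 2 and LPS. Genes with lower values included H2-Aa at 3516, 2460 and 52.7 CPM, Cd74 at 9572, 7517 and 361 CPM, Cx3cr1 at 361, 297 and 4.39 CPM and Hpgd at 329, 111 and 2.20 CPM.

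A pair of classes was found mainly in the LPS library. Neutrophil-like cells (3, 1 and 35 in the controls and LPS) held the calprotectin gene S100a9 at 139553 CPM with LPS. They were led by S100a8, Ngp, Retnlg and Camp, genes of granules and of maturing neutrophils. Mesothelial-like cells (2, 0 and 47) were led by Igfbp5, Hpgd, Igfbp6, Upk3b and Msln.

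Dendritic maturation genes were higher in phagocyte-like cells with LPS, and a few deep dendritic cells, free RNA or a response of the class to LPS may account for this. Free RNA was argued against, since it made up a median of 0.678% of the LPS UMIs of the 18 genes called. Without the dendritic sub-cluster of 7 cells, 14.7% of the class's LPS UMIs, 7 genes were still called (Il15ra, Cd40, Ccl22, Ccl17, Socs2, Ccl5 and Cd274). The median log2 fold change of the called genes went from 3.90 to 2.78 over the 13 still measured, or from 3.64 to 2.47 with genes at 0 set to their bound, with a median SE of 0.79. That outcome lay between those set for either reading. For 17 of the 18 genes (20 of all 21 measured in the list) the 7 cells held more than 14.7% of the LPS UMIs. The excess lay beyond the exact binomial 95% interval, with a median share of 80.3%. The cells were clustered on these counts, with Ccl17, Fscn1, Ccl22 and Ccr7 among their leading genes, so this cannot test an evenly shared response. In the other LPS cells 3 of the 18 (Ccr7, Cacnb3 and Tmem123) were not above both controls. A smaller response of those cells stays open for the rest of those no longer called, as Fscn1 kept 17 UMIs there against 0 and 0 in the controls (at least 5.26-fold, adjusted p = 0.0695).

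Matrix and contractile genes were lower in LPS endothelial-like cells, and free RNA or doublets from mural cells in the controls, or a response to LPS, may account for this. With free RNA subtracted, 8 of the 14 genes were still called (Col3a1, Eln, Tagln, Timp3, Sparc, Fbln5, Acta2 and Bgn). Their median log2 fold change went from -2.22 to -1.69 over the 12 still measured, with a median SE of 0.44, so free RNA and a response to LPS cannot be told apart. Removing the top 5% of doublet scores left 14 of 14 called, but it removed 0 endothelial-like barcodes in any library and says nothing about doublets. Named smooth muscle-like cells were found in control replicate 1 and pericyte-like cells in control replicate 2 alone, but unnamed clusters had leading genes of such cells too. These were Tagln and Acta2 in 155 barcodes of control replicate 2, Carmn and Dmd in 24 of control replicate 1 and Myh11, Tagln and Acta2 in near-empty LPS clusters.

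Output genes of the circadian clock (Dbp, Tef, Hlf, Nr1d1, Nr1d2, Per3 and Bhlhe41, chosen after their values were seen) were lower in LPS endothelial-like cells, with a median log2 fold change of -3.93, while the clock activator gene Arntl had 0, 0 and 54 UMIs (adjusted p = 1.17e-04). Free RNA in the control droplets was argued against, since 7 of 7 genes were still called with it subtracted and the median went to -4.18. In the other tested classes these genes lay below both controls in 6 of 6 (phagocyte-like), 7 of 7 (fibroblast-like) and 5 of 5 (lymphoid-like) measured, with medians of -1.92, -2.49 and -1.63, where 8 calls were lower and 0 higher. In lymphoid-like cells none was called, and the fall was mainly against control replicate 2 (Dbp at 11.3, 49.6 and 10.6 CPM). A candidate explanation is another time of day at harvest, an offset of the whole library. Harvest times are not given, and with 1 LPS library such an offset and a response to LPS cannot be told apart.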
